A study of Mus musculus with 12 samples.

How the data were processed

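The samples were liver and gonadal adipose tissue (GWAT) of male FVB mice, wild type or carrying a knockout of Cav1, the gene of caveolin-1, the main coat protein of the plasma membrane pits called caveolae. Per the labels, livers came from mice of 12 weeks and GWAT from mice of 8 weeks. Tissue was taken under anaesthesia at 3 PM, although the labels' treatment text speaks of livers alone. Per the labels' protocols, total RNA was extracted and checked on a Bioanalyser, and biotin-labelled cRNA was made for Illumina bead arrays. Each tissue had 3 arrays per genotype. The labels do not say whether the replicates were separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

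The deposited values used here were linear probe intensities for 45281 probes on each of 12 arrays. They were already quantile-normalized within each tissue, which was found from the values: the sorted intensities of the arrays differed by at most 0.384% in liver and 1.02% in GWAT, and the tissues held different distributions. No background had been subtracted, judging from lowest intensities of 84.0 in liver and 40.6 in GWAT. The software behind these steps is not given in the sources used here. A further 48 columns in 2 non-normalized tables were named by chip position only. They could not be matched to samples and were not used.

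Probes were named through the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Of the named probes, 34807 were matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6, which gave current symbols and was used beyond that only for which genes neighbour each other. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

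The plan had been to take background from negative control probes or detection p-values, which were not used here because their columns could not be matched to samples. The 1528 probes of olfactory, vomeronasal and trace amine receptor genes, which liver and fat are not known to express at high levels, stood in for negative controls. Intensities were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3 on these probes, with an offset of 16, and taken to log2. The planned quantile step was left out since the values already carried it. A probe counted as above background on an array when its intensity exceeded the 95th percentile of the receptor probes on that array. Probes above background on at least 3 of the 6 arrays of a tissue were kept, and the probe with the highest mean stood for its gene. For a gene below background on every array of a group, the fold is a lower bound, computed from the brighter group's mean against the dim group's background threshold or signal, whichever was higher on each array. This bound holds on the background-corrected scale alone.

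Genotypes were compared within each tissue with limma's lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. The difference between tissues was the interaction term of a limma fit over all 12 arrays and the genes measured by the same probe in both tissues. Shared calls were tested with Fisher's exact test, two-sided, per direction. A total of 38 gene lists, 25 of pathways and 13 of cell type markers, were tested with limma's camera at a preset correlation between genes of 0.01, with 35 lists applied to liver and 31 to GWAT. A list was tested with at least 3 measured members, and its p was adjusted over the lists of a tissue. The tests, the lists, the rule for naming genes and most alternatives were chosen before the data were examined.

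The rule named Cav1 and the measured caveola components, the 6 largest rises and 6 largest falls per tissue among genes past the threshold whose groups did not overlap and which were above background on every array of a genotype, and up to 2 members per list. For the difference between tissues it named 5 genes in each direction. Unannotated symbols were passed over. Genes named outside this rule are said to be chosen after their values were seen.

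The alternatives were no background correction, normexp without control probes at an offset of 50, no filter, a filter at the 99th percentile on every array of a genotype, the mean of a gene's probes, every probe tested on its own, no intensity trend, robust eBayes, array weights, the replicate number as a block, each array left out, all 12 arrays normalized together, camera with an estimated correlation, limma's fry, and an unadjusted p under 0.01 for the overlap. Turning the sign of the GWAT comparison was added after the data were seen. The main fits within tissues, the difference between tissues and camera with the preset correlation were tested on simulated data. The overlap and the alternatives were not. In simulated liver data of 9089 genes, 9.68% of genes changed 1.5-fold and 54.1% of those changed 2-fold were called, and 2 of 64 calls were unchanged genes. In simulated GWAT data of 11539 genes these shares were 29.6% and 69.8%, with 3 of 99 calls unchanged. For the difference between tissues, over 7995 genes, they were 15.6% and 56.0%, with 9 of 123 calls unchanged. The list test called the shifted list and 0 of 20 unshifted lists in each simulated tissue. Noise was simulated independently for each probe, so these runs do not show how the list test behaves where genes are correlated. In simulated GWAT 98 tested genes were changed 1.5-fold and 96 were changed 2-fold. That is far fewer than the 2886 called in the real GWAT data, so the shares given may not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.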

Results

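RNA levels were measured on 12 bead arrays of 45281 probes, 3 for each combination of tissue (liver or gonadal adipose tissue, GWAT) and labelled Cav1 genotype (wild type or knockout). The median intensity was 113 on the liver arrays and 69.2 on the GWAT arrays. Between 33.7% and 36.5% of probes lay above background on the liver arrays, and between 44.8% and 48.6% on the GWAT arrays. After the filter, 9033 genes were tested in liver and 11568 in GWAT. The comparison of genotypes in each tissue asks which transcripts differ when caveolin-1 is lost, and the knocked-out gene itself was examined first.

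Cav1 was lower in the knockout in liver but far higher in the arrays labelled knockout in GWAT. Its single probe, on a gene of chromosome 6, read 183 ± 23.8 (SD, n = 3) in wild-type liver and 114 ± 3.60 (SD, n = 3) in knockout liver, where it was below background on 3 of 3 arrays. The knockout mean was 0.620 of the wild-type mean in raw intensity. On the background-corrected scale the fall in liver was at least 2.89-fold (fitted log2 -1.80, SE 0.23, limma adjusted p = 0.0124), while the fitted log2 was -0.96 with an offset of 50 and -0.68 without correction. Its size thus depended on the background, and the adjusted p was 0.0634 without an intensity trend and 2.46e-04 to 0.0247 under the other settings over all arrays. It was 0.00333 to 0.0465 with 1 knockout array left out. With any wild-type liver array left out, Cav1 could not pass the filter, which still needed 3 arrays above background, so its fall was not tested there. In GWAT the probe read 110 ± 2.26 (SD, n = 3) on arrays labelled wild type, above background on 3 of 3, and 15729 ± 1535 (SD, n = 3) on arrays labelled knockout, a ratio of 143. On the log2 scale after background correction this was a rise of 7.87 (SE 0.08, limma adjusted p = 1.40e-12). Cav1 thus ran against the genotype labels on all 6 GWAT arrays. Every GWAT direction given here is that of the labels and would turn if the labels were exchanged.

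**Figure D1:**
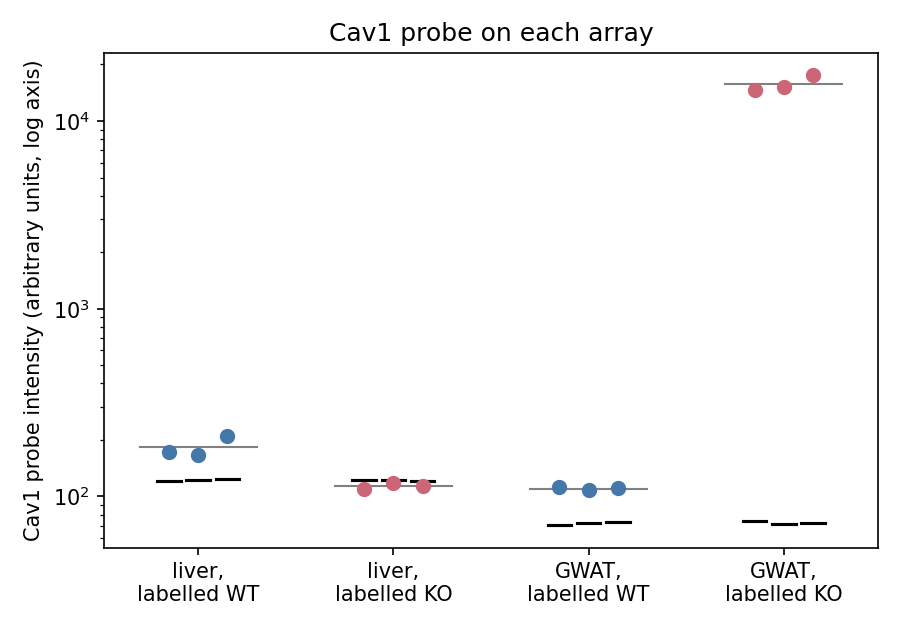
Intensity of the Cav1 probe on each of the 12 arrays, on a log axis, by tissue and labelled genotype; dots are arrays, grey lines group means and short black lines the background threshold of each array. In liver the knockout arrays lie below their thresholds, while in GWAT the arrays labelled knockout average 15729 and those labelled wild type 110.

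In liver few transcripts differed between genotypes. Besides Cav1, 3 genes fell and 5 rose in the knockout (n = 3 per genotype). The largest rises were in Cyp2b9, a cytochrome P450 that is higher in female than male mouse liver, at log2 1.80 (SE 0.29, adjusted p = 0.0271), and Wdr92, a WD-repeat protein, at log2 1.79 (SE 0.23, adjusted p = 0.0124). Acnat2, an acyltransferase that conjugates fatty acids with amino acids, rose by 1.48 (SE 0.23, adjusted p = 0.0196) and Cyp2b23, another cytochrome P450 of the same family, by 1.42 (SE 0.22, adjusted p = 0.0244). Lyz2, the lysozyme of macrophages, rose by 1.00 (SE 0.15, adjusted p = 0.0167). Rpa3, a subunit of the single-strand DNA-binding complex RPA encoded on chromosome 6 like Cav1, fell by 1.10 (SE 0.16, adjusted p = 0.0142). Kcnk5, a potassium channel, fell by 0.94 and Hes6, a transcriptional regulator, fell by 0.91, each with an adjusted p = 0.0142. The 9 calls were made among 9033 genes, of which 844 had an unadjusted p under 0.05, where chance alone gives 452. Several of these genes have probes that differ: the other Wdr92 probe read -0.27 (adjusted p = 0.749), the other Lyz2 probe 0.24 (adjusted p = 0.688), the other Kcnk5 probe -0.71 (adjusted p = 0.349), and the other Hes6 probes -0.03 and -0.13. The rise of Cyp2b9 was 0.91 without background correction (adjusted p = 0.0824) and 1.15 with an offset of 50 (adjusted p = 0.0683), and its call was lost with both. Cyp2b23 was above background on 1 of 3 wild-type arrays and lost its call without a filter (adjusted p = 0.0545). With the mean of a gene's probes, Cyp2b9, Wdr92, Lyz2, Kcnk5 and Hes6 did not pass (adjusted p 0.0743 to 0.472). A probe of Cyp2b9 or Cyp2b23 may also read near-identical copies of that family. The count was 0, 1 and 1 without wild-type replicates 1, 2 and 3, and 84, 3 and 29 without knockout replicates 1, 2 and 3. It was 4 with the mean of a gene's probes, 0 without an intensity trend, 14 with robust eBayes and 245 with array weights.

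**Figure D2:**
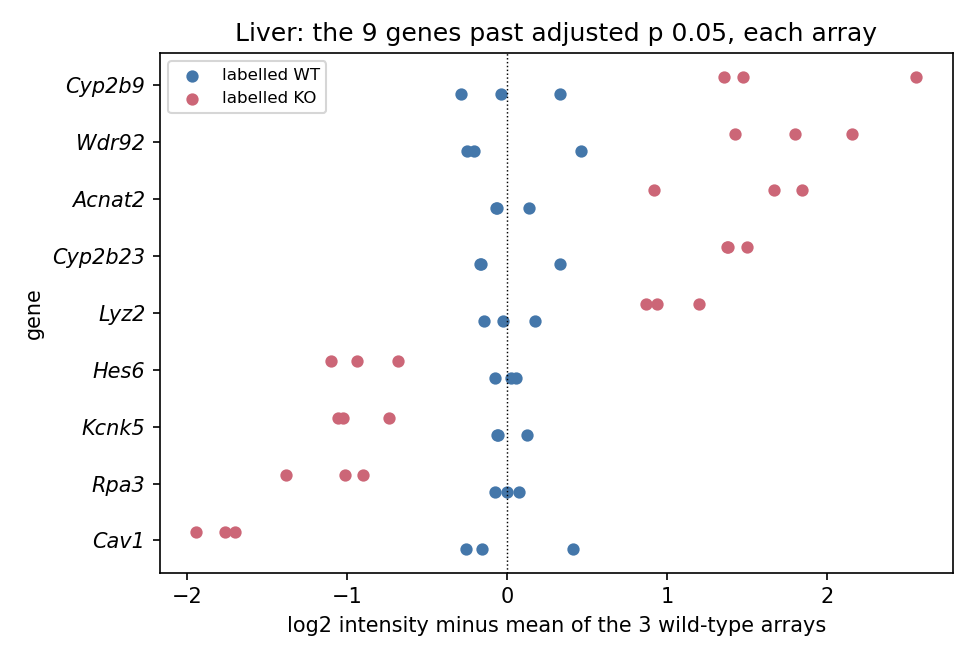
Log2 intensity of the called liver genes on each array, relative to the wild-type mean of the gene; dots are arrays, coloured by genotype. The 3 knockout arrays of each gene lie on one side of the 3 wild-type arrays, with Cyp2b9 at a mean of 1.80. The knockout arrays of Cav1 were below background, and their plotted distance from the wild type is the fitted one, which is larger than the lower bound.

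Small shifts of whole gene groups passed the list test in liver, although almost none of their members was called alone. Of 34 lists tested, 7 passed camera with the preset correlation, and 0 passed with an estimated correlation or with fry. Macrophage markers were shifted up (median log2 0.12, adjusted p = 0.00156), with 1 of 21 members risen (Lyz2), and the adjusted p = 0.589 with an estimated correlation. Hepatocyte markers (15 members, median 0.10, adjusted p = 0.0180) and mesothelial markers (4 members, median 0.24, adjusted p = 0.0228) were also shifted up, with 0 members called in each and an adjusted p = 0.589 with an estimated correlation. Upk3b, a marker of the mesothelium that covers the liver, read 1.24 (adjusted p = 0.111) and was past the threshold when adjusted over the list alone. Genes higher in male than female liver were shifted down (12 members, median -0.12, adjusted p = 0.0237; adjusted p = 0.589 with an estimated correlation). None of them was called over all genes and 1 was past the threshold adjusted over the list alone, the fatty acid hydroxylase Cyp4a12b, at -0.84 (adjusted p = 0.154). Respiratory chain subunits were shifted down (68 members, 0 called, median -0.09, adjusted p = 0.0487; adjusted p = 0.697 with an estimated correlation). Acute phase genes (22 members, median 0.07) and extracellular matrix genes (23 members, median 0.06) were shifted up, with 0 members called over all genes or adjusted over the list alone and an adjusted p = 0.0487 each. With an estimated correlation their adjusted p-values were 0.697 and 0.589. Without knockout replicate 1, which ended the macrophage call (adjusted p = 0.0622), 2 lists passed and the acute phase median turned to -0.061. Without knockout replicate 3 the respiratory chain median was -0.030 (adjusted p = 0.871), and without knockout replicate 1 the mesothelial median was 0.089 (adjusted p = 0.186). The respiratory chain call was also lost without wild-type replicate 1 (adjusted p = 0.317) or 3 (adjusted p = 0.0987), the mesothelial call without wild-type replicate 2 (adjusted p = 0.0597), and the acute phase call without wild-type replicate 2 or 3 or knockout replicate 1 (adjusted p 0.165 to 0.611). The matrix call was lost without knockout replicate 1 or 2 (adjusted p 0.0630 to 0.0973) and the male-biased call without wild-type replicate 3 or knockout replicate 1 or 2 (adjusted p 0.0550 to 0.134). Leaving out the intensity trend ended every call but that of macrophage markers (adjusted p 0.0619 to 0.181). Without a filter the acute phase, matrix and hepatocyte calls were lost (adjusted p 0.0753 to 0.335), and with a stricter filter the respiratory chain and acute phase calls (adjusted p = 0.0638). Array weights ended the respiratory chain, acute phase and mesothelial calls (adjusted p 0.0660 to 0.181). The matrix call was also lost without background correction (adjusted p = 0.0516) and with an offset of 50 (adjusted p = 0.0506).

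The other liver lists did not pass, with adjusted p-values from 0.175 to 0.932. Among caveola components 1 of 6 measured members changed, Cav1 itself, and the others read 0.51 for Cavin1, 0.03 for Cavin2, -0.04 for Cavin3, -0.17 for Pacsin2 and -0.27 for Pacsin3. In the list of female-biased genes 1 of 5 measured members rose, Cyp2b9, and the median of -0.22 and the mean of 0.20 differed in sign. Lists of fatty acid oxidation, lipid and cholesterol synthesis, glucose handling, bile acids and xenobiotic metabolism held 0 called genes. Their leading members were Acaa2 at 0.63 (adjusted p = 0.412), a beta-oxidation thiolase, Gys2 at 0.93 (adjusted p = 0.451), the liver glycogen synthase, and Cyp3a11 at 0.79 (adjusted p = 0.287), a drug-metabolising cytochrome P450. Adjusted over the list alone, 1 gene of the xenobiotic list was higher and 2 of the endothelial list, whose leading member Lyve1 read 1.16 (adjusted p = 0.287). Among exocrine pancreas markers 1 was lower when adjusted over the list alone, Cela1, at -0.35 (adjusted p = 0.477). The tricarboxylic acid cycle, mitochondrial ribosome, PPAR alpha, xenobiotic and unfolded protein lists also had a median opposite in sign to the mean and the test. Only 1 cholangiocyte marker was measured, so that list was not tested.

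In GWAT 24.9% of the tested transcripts differed between arrays labelled knockout and wild type. By the labels, which Cav1 contradicts, 1472 genes were higher and 1414 lower in the knockout, 2886 of 11568 tested. Of these, 82 were at least 2-fold higher and 141 at least 2-fold lower, and 4312 genes had an unadjusted p under 0.05, where chance gives 578. After Cav1, the largest rises were in Fxyd4, a regulator of the sodium pump, at log2 4.17 (SE 0.35, adjusted p = 3.15e-05), which was above background on 1 of 3 arrays labelled wild type, and Crygc, a lens crystallin below background on 3 of 3 arrays labelled wild type (adjusted p = 2.43e-05). Crygc rose at least 8.03-fold on the background-corrected scale, with a log2 of 2.22 without correction. Actg2, the smooth muscle gamma-actin, rose by 3.06 (SE 0.31), Serpina1d, a protease inhibitor of the alpha-1-antitrypsin family, by 2.52 (SE 0.15) and Aqp2, a water channel of duct epithelia, by 2.39 (SE 0.38). Itgad, a leukocyte integrin, was below background on 3 of 3 arrays labelled knockout on the brightest of its 4 probes (adjusted p = 3.32e-10). On that probe it was at least 38.8-fold lower on the background-corrected scale, with a log2 of -4.39 without correction. The other Itgad probes read -5.44, -2.63 and -0.72. With any array labelled wild type left out, the brightest probe had to fail the filter, which still needed 3 arrays above background. A dimmer probe then stood for Itgad and read -0.83 to -0.59, so these values do not test the fall on the brightest probe. Crygc had to fail the filter for the same reason with any array labelled knockout left out. Lower values were also found for Rnase2a, a ribonuclease of eosinophils (-3.51, SE 0.16), and Fgf13, an intracellular fibroblast growth factor homologue (-2.58, SE 0.16), which has 2 other probes, at -2.23 and -0.32 (adjusted p = 0.151). Cdsn, a cell adhesion protein of skin (-2.56, SE 0.17), Thbs1, a matrix glycoprotein (-2.51, SE 0.08), and Krt79, a keratin (-2.35, SE 0.16), followed. The count was 1659 without wild-type replicate 2, 1610 without knockout replicate 2 and 1864 without knockout replicate 3, all as labelled. Probes of 19 genes were called in opposite directions.

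By the labels, transcripts of mitochondrial energy metabolism were higher in the GWAT arrays labelled knockout, the arrays with high Cav1. Of 68 respiratory chain subunits, 46 rose, 0 fell and 22 did not pass, with 52 risen when adjusted over the list alone (median log2 0.31, adjusted p = 7.56e-15; adjusted p = 0.0365 with an estimated correlation). Sdhb, the iron-sulfur subunit of succinate dehydrogenase, rose by 0.85 (SE 0.08), with its other probes at 0.92 and 0.34 (adjusted p = 0.178). Atp5a1, an ATP synthase subunit, rose by 0.90 (SE 0.19) on its brighter probe but fell by 0.59 on its other, and did not pass with the mean of both (adjusted p = 0.482). Of 16 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 9 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.36, adjusted p = 7.00e-05; adjusted p = 0.0967 with an estimated correlation). Suclg1, a subunit of succinyl-CoA ligase, rose by 0.68 (SE 0.11) and Idh2, the mitochondrial isocitrate dehydrogenase, by 0.76 (SE 0.20). Of 17 genes of fatty acid oxidation, 11 rose and 0 fell, the same counts as adjusted over the list alone (median 0.39, adjusted p = 7.00e-05; adjusted p = 0.309 with an estimated correlation). They included the dehydrogenase Acadl at 0.71 (SE 0.11) and the carnitine palmitoyltransferase Cpt1b at 0.69 (SE 0.15), whose other probe read 0.27 (adjusted p = 0.374). Of 37 genes of the mitochondrial ribosome and import, 14 rose and 1 fell, against 15 and 1 adjusted over the list alone (median 0.22, adjusted p = 7.00e-05; adjusted p = 0.287 with an estimated correlation). Among them were the rRNA methyltransferase Tfb1m at 0.59 (SE 0.17) and the import subunit Timm50 at 0.52 (SE 0.13). Skeletal muscle markers moved the same way: 4 of 9 rose and 0 fell, and 7 rose adjusted over the list alone (median 1.28, or 1.16 with Mylpf, which was below background on the arrays labelled wild type, at its bound; adjusted p = 5.56e-04, adjusted p = 0.464 with an estimated correlation). The fast-muscle troponin Tnnc2 rose by 2.31 (SE 0.16) and the skeletal actin Acta1 by 1.35 (SE 0.15). Idh2 lost its call without wild-type replicate 2 (adjusted p = 0.0742), Timm50 without knockout replicate 2 (adjusted p = 0.0552) or 3 (adjusted p = 0.0596), and Tfb1m without any of wild-type replicates 2 and 3 and knockout replicates 1 and 3 (adjusted p 0.0540 to 0.0982).

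Transcripts of the extracellular matrix and of macrophages were lower in the GWAT arrays labelled knockout, again with the direction of labels that Cav1 contradicts. Of 33 matrix genes, 20 fell, 0 rose and 13 did not pass, and adjusted over the list alone 21 fell and 2 rose (median -0.38, adjusted p = 8.02e-10; adjusted p = 0.0365 with an estimated correlation). Thbs1 fell by 2.51 (SE 0.08) and Col5a3, a fibrillar collagen chain, fell by 1.88 (SE 0.12). Of 24 macrophage markers, 13 fell and 0 rose, and 14 fell adjusted over the list alone (median -0.30, adjusted p = 2.72e-06; adjusted p = 0.392 with an estimated correlation). Lgals3, a galectin of activated macrophages, fell by 1.62 (SE 0.16) and Trem2, a lipid-sensing receptor of macrophages, fell by 1.01 (SE 0.11). Of 11 markers of granulocytes and mast cells, 6 fell and 2 rose, the same counts as adjusted over the list alone (median -0.69, adjusted p = 0.0476; adjusted p = 0.432 with an estimated correlation). The mast cell tryptase Tpsb2 fell by 1.51 (SE 0.14) and Retnlg, a resistin-like protein of neutrophils, fell by 1.23 (SE 0.20). The granulocyte and mast cell call was lost without wild-type replicate 1 (adjusted p = 0.121), 2 (adjusted p = 0.0881) or 3 (adjusted p = 0.0609), without a filter (median 0.0044, adjusted p = 0.270), without an intensity trend (adjusted p = 0.0635) and with array weights (adjusted p = 0.0804).

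**Figure D3:**
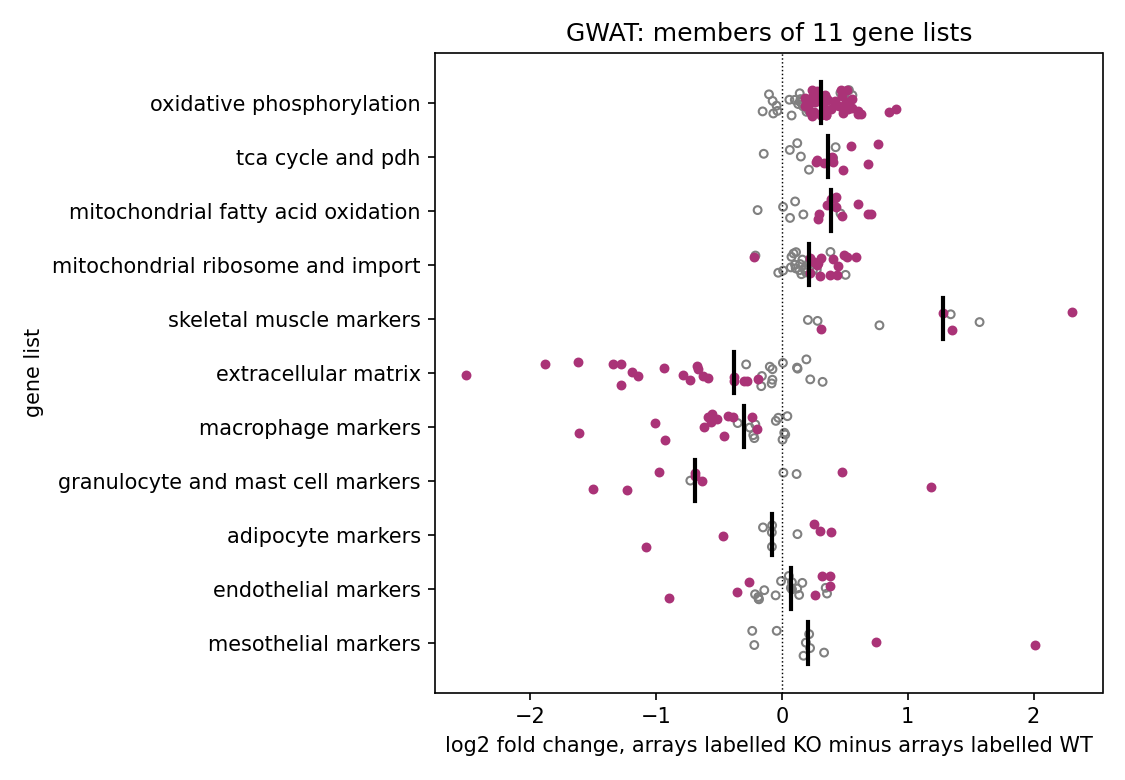
Log2 fold change (arrays labelled knockout minus arrays labelled wild type, GWAT) of each measured gene of the 8 lists that passed the list test and of the adipocyte, endothelial and mesothelial lists, which did not; filled dots passed an adjusted p of 0.05, open dots did not, and black bars mark list medians. Medians run from 1.28 for skeletal muscle markers to -0.69 for granulocyte and mast cell markers, and Cav1 contradicts the labels that set the sign.

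The other 23 GWAT lists did not pass, and many held genes that moved both ways. Beside Cav1, the caveola components Cav2 (0.59, SE 0.11), Cavin1 (-0.60, SE 0.10) and Cavin3 (-0.35, SE 0.07) changed, and the other 5 of 9 measured did not pass. Of 24 adipogenic and lipid droplet genes, 7 rose and 6 fell; the adipokine Retn fell by 1.08 (SE 0.11) and the lipid droplet protein Cidea rose by 0.78 (SE 0.23). Of 10 adipocyte markers, 3 rose and 2 fell (median -0.08), among them the lipid droplet protein Cidec at -0.46 (SE 0.10). Of 9 brown and beige fat genes, 4 rose and 1 fell; the cytochrome oxidase subunit Cox8b rose by 2.23 (SE 0.15) and the transcription factor Tbx1 fell by 0.98 (SE 0.17). Glycolysis genes went 4 up and 4 down, with the pyruvate kinase Pkm at -0.89 (SE 0.08) and the aldolase Aldoa at -0.71 (SE 0.06). PPAR alpha targets went 5 up and 5 down, with Pdk4, a kinase that restrains pyruvate dehydrogenase, at -1.32 (SE 0.09) and the coactivator Ppargc1a at 0.79 (SE 0.13). Lipid synthesis genes went 5 up and 2 down, with Thrsp at 0.72 (SE 0.11). Cytokines and chemokines went 4 up and 8 down, with Cxcl9 at 1.41 (SE 0.11) and Ccl8 at -1.38 (SE 0.22). Antioxidant genes went 5 up and 2 down, with the extracellular superoxide dismutase Sod3 at -1.11 (SE 0.11). Fibroblast and mural markers went 7 up and 6 down, with Cspg4 at -1.36 (SE 0.13) and Col1a1 at -1.34 (SE 0.14). Adjusted over the list alone, the counts were the same for the adipogenic, adipocyte, brown fat, glycolysis and PPAR alpha lists. They were 5 up and 3 down for lipid synthesis, 6 and 10 for cytokines, 6 and 2 for antioxidant genes, and 8 and 7 for fibroblast and mural markers.

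Further GWAT lists that did not pass also held called genes, given here in the direction of the labels, which Cav1 contradicts. Endothelial markers went 4 up and 3 down of 23, clock genes 4 and 1 of 12, and unfolded protein response genes 3 and 5 of 19. Genes next to Cav1 went 2 up and 1 down of 9, with Mdfic at 0.76 (SE 0.19) and the growth factor receptor Met at -0.72 (SE 0.14). Cholesterol synthesis (17 measured), interferon response (20), cell cycle (24), lymphocyte markers (11) and exocrine pancreas markers (4) each had 1 gene up and 1 down. The cholesterol gene Sc5d rose by 0.87 (SE 0.11). Mesothelial markers went 2 up and 0 down of 10 (median 0.20), with the keratin Krt14 at 2.01 (SE 0.29), and hepatocyte markers 2 up and 1 down of 8. No erythroid marker of 6 and no epididymis or testis marker of 7 was called by limma, and the epididymis and testis median of 0.23 was opposite in sign to the mean and the test. The PPAR alpha, glycolysis, antioxidant and cell cycle lists also had a median, mean and test that differed in sign. Adjusted over the list alone, the endothelial counts were 5 and 3, hepatocyte 2 and 2, lymphocyte 0 and 0, and cholesterol, interferon and cell cycle each 1 up and 0 down, and in the other lists of this paragraph they were those over all genes. Calls of Mdfic were lost without any of wild-type replicate 2 and knockout replicates 2 and 3 (adjusted p 0.0522 to 0.0704), and those of Cidea without wild-type replicate 3 or knockout replicates 2 or 3 (adjusted p 0.0712 to 0.109). Without a filter neither these nor Tfb1m passed (adjusted p 0.0528 for Mdfic, 0.0628 for Cidea and 0.0858 for Tfb1m), and robust eBayes ended the calls of Cidea (adjusted p = 0.135) and Idh2 (adjusted p = 0.0782). Cidea also lost its call without an intensity trend (limma adjusted p = 0.0705).

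The difference between tissues was tested gene by gene. Of 8058 genes measured with the same probe in both tissues, 620 had a labelled knockout difference that itself differed between tissues, 357 more positive in GWAT and 263 more negative, and 1925 had an unadjusted p under 0.05. Apart from Cav1 (9.67, SE 0.23, with a liver knockout group below background), and with the GWAT sign of the labels, the largest positive differences, GWAT minus liver, were in Serpina1d (2.55, SE 0.17), the muscle myosin light chain Myl4 (2.29, SE 0.30), the lipid transporter Mfsd2a (2.27, SE 0.52) and the chemokine Cxcl9 (1.74, SE 0.20). The largest negative differences were in Nipal1 (-2.64, SE 0.36), the immediate early genes Egr1 (-2.26, SE 0.49) and Fos (-2.23, SE 0.56), Rgs1, a regulator of G protein signalling (-2.14, SE 0.42), and Net1 (-1.99, SE 0.26). Each of these 10 genes was past the threshold in GWAT by its labels, and Cav1 alone was past it in liver. If the sign of the GWAT comparison was turned, because Cav1 contradicts its labels, 634 genes differed. Cav1 (-6.06), Serpina1d (-2.50), Myl4 (-1.25) and Cxcl9 (-1.09) then passed with a negative difference and Net1 (1.18) with a positive one. Egr1 (-0.07, adjusted p = 0.949), Fos (adjusted p = 0.711), Rgs1 (adjusted p = 0.165), Nipal1 (adjusted p = 0.0969) and Mfsd2a (adjusted p = 0.0909) then no longer passed. With robust eBayes, Egr1 (adjusted p = 0.0882), Mfsd2a (adjusted p = 0.0947) and Fos (adjusted p = 0.123) did not pass. Fos also lost its call without a filter (adjusted p = 0.0538), without an intensity trend (adjusted p = 0.0559) and without any of liver wild-type replicates 1 and 2 and GWAT replicate 1 of either label (adjusted p 0.0565 to 0.0624). Tissue was confounded with age and with separate normalization of the tables. The count was 1006 without background correction and 1814 with array weights, 936 without liver knockout replicate 1, and 366, 302, 282 and 311 without GWAT wild-type replicates 1 and 2 and knockout replicates 2 and 3.

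Few genes were called in both tissues. Among 8582 genes tested in both, 0 were called higher in both and 0 lower in both at an adjusted p under 0.05 (limma; 6 liver calls could have been shared, of which 2 higher and 4 lower). With the GWAT sign turned, 2 of the 4 genes lower in liver, Cav1 and Rpa3, were also lower in GWAT, against 0.576 by chance (Fisher's exact test, odds ratio 5.95, p = 0.102, adjusted p = 0.271 over 8 tests). At an unadjusted p under 0.01, 28 genes were higher in both tissues as labelled, against 14.7 by chance (odds ratio 2.25, exact p = 5.70e-04, adjusted p = 0.00456). They included Acaa2, Gys2 and the ATP synthase subunit Atp5pb, chosen after their values were seen. At the same threshold 7 genes were lower in both, against 7.52 by chance (exact p = 1). With the GWAT sign turned, 20 were higher in both against 12.9 by chance (exact p = 0.0505, adjusted p = 0.202) and 8 lower against 8.54 (exact p = 1). Fisher's exact test counts genes as independent units, so its p-values do not measure the spread between samples.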

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

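The test on genes near Cav1 and the counts over other splits of the arrays were fixed before their results were seen. The tests of the probe, of adipocyte share, of striated muscle, of epithelium and of smooth muscle, and the turned GWAT sign, were chosen only after the results were seen.

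A difference between tissues in the labelled knockout effect drew attention to 620 genes, by an interaction test in limma. The differences, GWAT minus liver on the log2 scale, were 9.67 for Cav1, 2.55 for Serpina1d, 2.29 for Myl4, 2.27 for Mfsd2a and 1.74 for Cxcl9. They were -2.64 for Nipal1, -2.26 for Egr1, -2.23 for Fos, -2.14 for Rgs1 and -1.99 for Net1. With the GWAT sign turned, those of Cav1 (-6.06), Serpina1d (-2.50), Myl4 (-1.25), Cxcl9 (-1.09) and Net1 (1.18) passed with the opposite sign and those of the other 5 did not pass, and each value of Cav1 rests on a liver knockout group below background. In 100 drawn of 200 possible splits within both tissues, the real split alone (1 of 100) gave as many genes, and the highest other gave 560. That other split kept the GWAT grouping, as 11 of the drawn splits did including the real one; with another GWAT grouping at most 1 gene was called. The split that turns the GWAT groups was not among those drawn and gave 634 genes, more than the real one. The count thus followed the grouping of the GWAT arrays, for which 10 splits are too few for a share under 0.05, and the 1 of 100 excludes chance neither for that grouping alone nor for the liver groups.

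Cav1 in GWAT ran against the genotype labels of 6 of 6 arrays. A probe outside the deleted part of the gene, reading a leftover transcript near the wild-type level, is argued against, since 0 of 3 liver arrays labelled knockout had the probe above background. A smaller leftover could not be seen in liver, where the wild-type mean was 183 against thresholds of 121 to 124. A candidate explanation is that the genotype labels of all 6 GWAT arrays are exchanged: a knockout allele brings its flanking DNA into every tissue, so genes within 20 Mb of Cav1 that differed in liver (unadjusted p under 0.01) would then move the opposite way in GWAT by label, and 2 of 4 did, Ppp1r9a (1.20 in liver, -0.36 in GWAT, adjusted p = 0.0137 there) and Rpa3 (-1.10 and 0.58, adjusted p = 0.00117), while Pon2 (-0.35 and -0.18) and Cnot4 (-0.58 and -0.05) did not pass in GWAT, and elsewhere 67 of 169 such genes were opposite. The fold changes in the tissues correlated at r = -0.81 across the 4 genes, which are not independent replicates, and at 0.13 elsewhere: the correlation had the sign that an exchange predicts but the count reached no majority, so with 4 genes exchanged labels and labels that hold cannot be told apart by this test, and under an exchange the probe would read above background on 3 of 3 knockout GWAT arrays (108 to 112 against thresholds of 70.3 to 72.7), unlike liver, a low signal whose source was not tested. The Cav1 values themselves argue against labels that hold on these 6 arrays. A loss of the gene would lower the probe, yet it read 14598 to 17476 on arrays labelled knockout and 108 to 112 on those labelled wild type. A rise of Cav1 in knockout fat would need the probe's target in mice that carry the knockout, and meets the objection from liver in so far as both tissues came from the same knockout line and liver signal close to background can show it.

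Macrophage and matrix genes were lower and mitochondrial genes higher in the GWAT arrays labelled knockout. A larger share of adipocytes in those arrays would lower the markers of every other cell type alike. Yet the mean of 44 endothelial, lymphocyte and mesothelial markers was not lower there, at 8.37 ± 0.021 against 8.28 ± 0.028 (SD, n = 3). These 44 included the keratin Krt14, which rose by 2.01 and is also an epithelial marker. The mean of 24 macrophage markers minus that of the 44 differed by -0.48 (0.55 ± 0.087 against 1.03 ± 0.12, SD, n = 3), with no overlap between arrays. This argues against that share as the whole cause of lower macrophage markers. The measure was changed after its values were known, however, and single genes spread widely (medians -0.30 and 0.10, SD 0.41 among the 44). Striated muscle carried into the arrays labelled knockout may add mitochondrial transcripts: the mean log2 of muscle markers was 6.66 to 6.71 on arrays labelled wild type and 7.23, 7.56 and 8.41 on those labelled knockout, and respiratory chain means were at most 11.06 and then 11.28, 11.35 and 11.36 in the same array order, a smaller spread than that of the muscle markers, while the abundant muscle actin Acta1 averaged 9.05 and 10.4. The unequal spread goes against muscle as the whole source, but with 3 arrays and 0 labelled knockout that had muscle markers within the wild-type range and respiratory chain genes above it, striated muscle and a change within fat cells cannot be told apart. The genotype itself stays an open, untested explanation in either direction of the labels. For GWAT, 1 of 10 splits gave as many genes (2886, highest other 1), and for liver 1 of 10 (9, highest other 2), where 10 splits are too few for a share under 0.05. As many lists passed in 2 of 10 GWAT splits (8, highest other 8) and in 1 of 10 liver splits (7, highest other 6). A GWAT split that mixed the labels thus gave as many lists as the labelled one. The number of GWAT lists past camera with the preset correlation therefore did not set the labelled grouping apart, and for liver lists 10 splits are again too few.

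Genes of duct epithelium and smooth muscle were among the largest rises in the GWAT arrays labelled knockout. Epithelium of the neighbouring reproductive tract carried into those arrays stays open. Of 18 epithelial genes, with a median of 0.045, 6 rose, all of them seen beforehand, among them Fxyd4 and Aqp2. The other 12 had a median of -0.057, but they varied together (estimated correlation 0.75), so that median is a weak guide. Krt8 and Krt18 among these 12 also belonged to the mesothelial list tested earlier. Of 7 epididymis and testis markers, a list fixed beforehand, 0 were called, with a median of 0.23 and a mean of -0.0058. Epithelial genes with low signal on arrays labelled wild type went both ways. Cldn4 (5.09 there and 7.07 on arrays labelled knockout) and Slpi (4.76 and 6.15) rose, while Cdh1 (6.13 and 6.10) and Cldn7 (5.92 and 5.92) did not. The brighter keratin Krt8 (9.47 and 9.25) did not rise either. The levels that a given share would bring are not known, so carried-in epithelium and a change in the fat cannot be told apart. Smooth muscle carried into the arrays labelled knockout may contribute. With genes seen among the largest changes left out, 10 smooth muscle genes had a median of 0.40, with 5 risen and 0 fallen. Acta2 and Tagln among them belonged to the fibroblast and mural list tested earlier, so the 10 genes were not wholly unseen. The abundant smooth muscle actin Acta2 averaged 13.0 and 13.5, and the listed smooth muscle genes were above background on at least 2 of 3 arrays labelled wild type. The set of 10 genes passed camera (adjusted p = 0.0190) but not with an estimated correlation (adjusted p = 0.457), so smooth muscle from vessels or ducts and a change in the fat cannot be told apart.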

How the results depend on the processing

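Most settings were chosen before the data were examined. The turned GWAT sign was not, nor were the receptor probes and percentiles behind the background and filters, which replaced the planned negative controls and detection p-values. The liver count of 9 genes became 4 with the mean of a gene's probes, 0 without an intensity trend (793 genes at an unadjusted p under 0.05), 14 with robust eBayes and 245 with array weights, and 0 to 84 with 1 array left out. The fall of Cav1 in liver, -1.80, was -0.68 without background correction and -0.96 with an offset of 50. It kept its size without an intensity trend but not its call (adjusted p = 0.0634), and stayed between -1.85 and -1.73 with 1 knockout array left out. With 1 wild-type array left out Cav1 could not pass the filter, which still needed 3 arrays above background, so its fall was not tested. The GWAT count of 2886 was 2200 to 3924 under the other settings and 1610 to 2725 with 1 array left out, and Cav1 in GWAT stayed between 7.09 and 7.92. The interaction count of 620 became 1006 without background correction, 1814 with array weights and 634 with the GWAT sign turned, and was 282 to 936 with 1 array left out. The overlap of 0 genes became 1 without a filter, 2 with robust eBayes, 57 with array weights, 35 at an unadjusted p under 0.01 and 2 with the GWAT sign turned, and was 0 to 19 with 1 array left out. Liver lists past the threshold, 7, became 4 without a filter, 1 without an intensity trend, 0 with an estimated correlation and 0 with fry, and 2 to 7 with 1 array left out; GWAT lists, 8, became 2 with an estimated correlation, 10 with fry and 7 to 9 with 1 array left out. The median of the acute phase list in liver turned to -0.061 without liver knockout replicate 1 and reached 0.18 without replicate 3. Fewer arrays may explain part of the losses with 1 array left out, but this was not tested. The liver count rose to 84 without knockout replicate 1 and to 29 without knockout replicate 3. For the other settings the cause was not tested either. Called genes named in GWAT kept their call in 656 of 690 values under other settings and in 357 of 411 with 1 array left out. In liver they did so in 73 of 90 and 22 of 51, and 0 reversed in either tissue. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.017, -0.021 and 0.0061 in liver and 0.016, -0.012 and 0.15 in GWAT. With the replicate block the liver count was 21, the GWAT count 2793 and the overlap 1, and the calls of the liver matrix list (adjusted p = 0.0652), of the GWAT granulocyte and mast cell list (adjusted p = 0.0600) and of Fos between tissues (adjusted p = 0.0507) were lost, among others. Scaling to a common median and the authors' processed values were not run, since the input already was those values with equal medians, nor was a slide block, since the columns that name a chip could not be matched to samples. Robust eBayes and single probes gave no list test. Signal over background limited Cav1 in liver, where the wild-type mean of 183 stood against thresholds of 121 to 124.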

Other observations

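The lists and genes in this part were chosen only after the largest changes had been seen, so their tests describe these arrays and are not independent evidence. In GWAT, by labels that Cav1 contradicts, genes of branched-chain amino acid breakdown were higher in the arrays labelled knockout: 12 of 16 rose and 0 fell (median log2 0.54, adjusted p = 4.34e-07; adjusted p = 0.0765 with an estimated correlation). Mccc2, a subunit of methylcrotonyl-CoA carboxylase, rose by 0.93 (SE 0.11), the acyl-CoA dehydrogenase Acadsb by 0.93 (SE 0.16), Dbt, a subunit of the branched-chain ketoacid dehydrogenase, by 0.71 (SE 0.08), and the isovaleryl-CoA dehydrogenase Ivd by 0.55 (SE 0.09). In liver 0 of the 16 genes were called by limma (median -0.03, adjusted p = 0.996).

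Immediate early genes, which are induced within minutes of a stimulus, were lower in the GWAT arrays labelled knockout: 10 of 17 fell and 0 rose (median -0.47, adjusted p = 2.87e-05; adjusted p = 0.182 with an estimated correlation). Fosb fell by 2.14 (SE 0.23), Fos by 1.32 (SE 0.32), Junb by 1.23 (SE 0.21) and Egr1 by 1.09 (SE 0.17). In liver 0 of 10 measured members were called (median 0.21, adjusted p = 0.712). Smooth muscle markers went 8 up and 0 down of 13 in GWAT (median 0.54, adjusted p = 5.62e-04; adjusted p = 0.457 with an estimated correlation), and epithelial markers 6 up and 0 down of 18 (median 0.05, adjusted p = 0.0507).

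On the liver arrays, knockout replicate 3 lay apart on the first principal component, which held 36.3% of the variance, with the highest score, while the other 5 arrays lay between -11.2 and 4.54. On the second component (22.1%), liver knockout replicate 1 had the lowest score, -19.5, and the other arrays lay between -9.63 and 12.2. In GWAT the first component held 54.3% and separated the arrays by label, from -29.3 to -13.8 for those labelled wild type and from 18.1 to 23.9 for those labelled knockout. On the second (20.9%), the array labelled wild-type replicate 1 had the highest score, 23.7, and the other arrays lay between -16.2 and 3.80.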
